A study of Homo sapiens with 6 samples.

How the data were processed

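Total RNA from U87 cells, an established human glioma line, was hybridised as biotin-labelled cRNA to 6 Affymetrix expression arrays. Per the labels, 3 arrays carried RNA from cells given a lentivirus with a short hairpin RNA against PCGF1 and 3 carried RNA from cells given a negative control lentivirus. Both kinds of cells grew in DMEM with fetal bovine serum, and RNA was isolated with Trizol, per the labels' protocols. The labels number the arrays of each group 1 to 3 and call them biological replicates. Nothing in the sources used here says that they came from separate cultures, so p-values measure the spread between these samples, which may be partly technical. The sample names also carry T0 for every knockdown array and T1 for every control array, with no explanation, so whatever T0 and T1 stand for cannot be separated from the knockdown.

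The deposited table gives 1 log2 value per probe set and array. Per the submitters' processing notes the authors used RMA, which corrects background, normalizes the arrays together and summarises the probes of a probe set on the log2 scale; no version is given. The table does not record the log base, so log2 is taken from the naming of RMA, and folds printed here rest on it. The values themselves show a further step that no source describes. Each probe set had been centred so that the median of its 6 arrays was 0, and the largest departure from 0 was 4.85e-07. The table therefore holds differences from that median and no absolute signal, so that neither a probe set's brightness nor its distance from background is known. The medians of the 6 arrays lay between -0.00238 and 0.00399, and no second normalization was applied. The direction is set by the array labels, and PCGF1 itself was lower in the arrays labelled as knockdown. All 6 columns of per-sample values were used.

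The table held 49395 probe sets. After 102 Affymetrix control probe sets were left out, 49293 were tested. In the platform annotation, which can be old, 44988 of these had 1 gene symbol, 1832 had several and 2473 had none, and no gene was named from a probe set with several symbols. Gene IDs of 44961 single-symbol probe sets were found in the RefSeq gene table of the GRCh38.p14 assembly, and 0 symbols differed. That table was also used for older symbols of list members and for which genes neighbour each other, and its coordinates are not given because no genome build is named for the arrays. A gene's value on each array was the mean of all its single-symbol probe sets, which gave 18132 genes, 11734 of them with 2 or more probe sets. The plan fixed before the data were examined took the brightest probe set per gene, and averaging was its alternative. Centred values have no brightness, so averaging was used and the probe sets without averaging became the alternative. For the same reason 2 planned filters on dim probe sets, an intensity trend in the variance model and the brightness condition in the rule for named genes could not be applied.

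Knockdown was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates) on all 6 arrays. P-values were adjusted by the Benjamini-Hochberg method over all 18132 genes, and a gene was called changed at an adjusted p under 0.05. Standard errors are limma's moderated ones, and 95% intervals use the same spread. PCGF1 was in addition tested by a two-sided exact permutation test, which with 3 against 3 arrays cannot give a p under 0.1. The number of arrays limits the precision of each value.

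The members of 44 gene lists were fixed before the data were examined, 1238 entries of which 1145 were measured, and a gene can be in several lists. The lists cover Polycomb complexes and their targets, the cell cycle, stress, inflammatory and metabolic responses, matrix and adhesion, signalling pathways, neural lineages and the markers of epithelial, leukocyte and endothelial cells. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 44 lists. Camera with a correlation estimated for each list and fry, which asks whether a list's genes move on balance one way, were alternatives. Members were also counted with p-values adjusted over the list alone. Intervals of list medians are 95% bootstrap intervals over genes from 2000 draws, and genes are not independent replicates.

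The genes named were set by a rule written before the data were examined. It takes PCGF1 and the members of its complex, the 12 genes with the largest rise and the 12 with the largest fall among called genes whose groups did not overlap, up to 2 risen and 2 fallen members of each called list by size, and at most 2 members of each other list. Genes outside the rule are said to have been chosen after their values were seen. Some genes that the rule picks are left out of the text.

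Alternatives tried were quantile normalization, centring of each array on its median, array weights, the replicate number as a block, each array left out in turn, stricter thresholds, a test against a 1.2-fold change, and probe sets without averaging. Chosen after the data were seen were a robust variance model, the most variable probe set of each gene, and averaging without the probe sets whose names end in _s_at or _x_at, which can match several transcripts. The steps were tested on simulated data built from the residual spread of these arrays for the comparison of knockdown with control over 18132 genes. Planted changes of 0.25 on the log2 scale were recovered in 46.3% of cases, those of 0.5 in 83.6% and those of 1 in 100%. Of 157 calls 4 were false, and the planted list was called with 0 of the other lists. Simulated genes varied independently, and the planted list was shifted by 0.5, more than the median of any called list. The simulation therefore does not show how the list test behaves with correlated genes or smaller shifts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The sequence of the hairpin was not used here, so matches of it to other transcripts were not examined.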

Results

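Gene expression was measured on 6 Affymetrix arrays in U87 cells, a human glioma line that grows as an adherent culture. In 3 arrays the cells carried a lentiviral short hairpin RNA against PCGF1, and 3 arrays came from cells with a negative control lentivirus. PCGF1 is a Polycomb group RING finger protein that forms, with BCOR or BCORL1, KDM2B and other subunits, the repressive chromatin complex PRC1.1. The design names 1 comparison, which asks which genes differ between PCGF1 knockdown and control cells. Values are log2 signals relative to the median of the 6 arrays, so they show differences between arrays and not how strongly a gene is expressed. Arrays of the same group resembled each other. The first principal component held 47% of the variance and separated knockdown from control arrays, and the next held 15.2%. No arrays were duplicates, the smallest root mean square difference between 2 of them being 0.135.

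PCGF1 transcript was lower in the knockdown arrays, at 74.3% of the control level (95% interval 67.8 to 81.5%). Its log2 signal was -0.27, -0.13 and -0.19 in knockdown replicates 1 to 3, against 0.13, 0.27 and 0.29 in the control replicates. The group means were -0.20 ± 0.07 and 0.23 ± 0.09 (SD, n = 3 each). The log2 fold change was -0.43 ± 0.06 (SE, limma, adjusted p = 0.00410), and the exact permutation test gave the smallest p possible with 3 against 3 arrays, 0.1. The value rests on 1 probe set, and PCGF1 was number 82 among fallen genes by size of change.

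Of the 9 measured members of PRC1.1, PCGF1 included, 1 rose and 2 fell, and the same counts were obtained when p-values were adjusted over the list alone. RYBP, a subunit shared by several variant PRC1 complexes, fell by 0.27 on the log2 scale (SE 0.04, adjusted p = 0.00468), with all 4 of its probe sets lower. BCOR, the scaffold of the complex, rose by 0.20 (SE 0.04, adjusted p = 0.0275), a call that was lost when any 1 of the 6 arrays was left out (adjusted p 0.0558 to 0.0826), with the replicate number as a block (adjusted p = 0.0720) and with the most variable probe set of the gene (adjusted p = 0.225). Log2 fold changes of the others were -0.08 for YAF2, -0.05 for SKP1, -0.02 for BCORL1, -0.01 for KDM2B, 0.03 for RING1 and 0.04 for USP7, none of which passed the test (adjusted p 0.307 to 0.916). The list as a whole was not called (adjusted p = 0.431). Among the other PRC1 subunits 0 of 22 rose and 1 fell (list adjusted p = 0.918), and among the PRC2 subunits 1 of 12 rose and 1 fell (list adjusted p = 0.290).

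**Figure D1:**
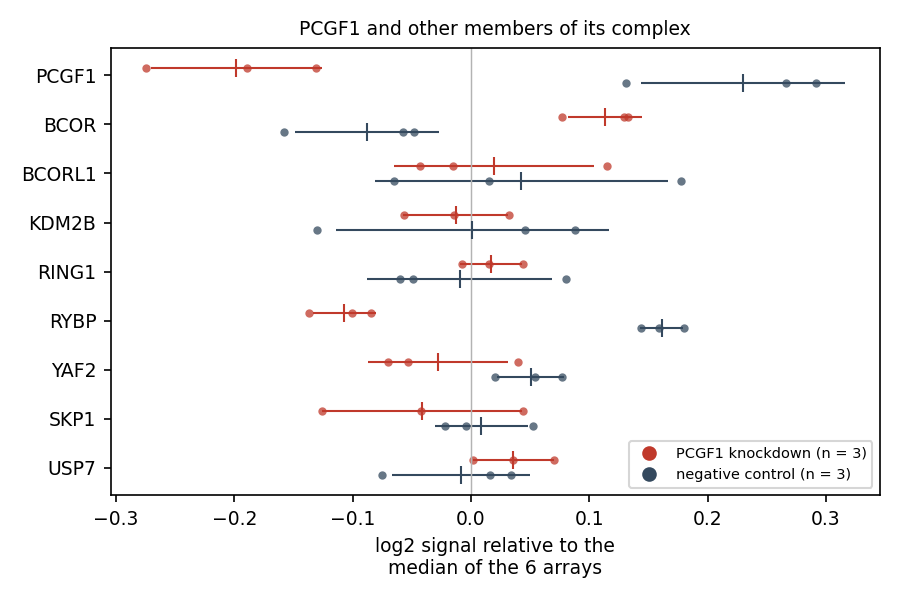
Log2 signal of PCGF1 and the other measured PRC1.1 members relative to the median of the 6 arrays (horizontal axis), averaged over the probe sets of each gene. Points are arrays, ticks are means of 3 arrays and horizontal bars are SD; PCGF1 lies between -0.27 and -0.13 in the knockdown arrays and between 0.13 and 0.29 in the control arrays.

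Across the 18132 genes tested, 1154 were higher and 840 lower in the knockdown arrays, 1994 in all or 11%. Most changes were small. The median log2 fold change was 0.24 among risen genes and -0.23 among fallen genes, and 63 genes changed at least 1.5-fold. With probe sets averaged, 4 genes changed at least 2-fold and all of them fell, but risen genes joined them under other settings, with 7 higher and 8 lower for the most variable probe set of each gene, 2 and 5 without the _s_at and _x_at probe sets, 8 and 16 as single probe sets, and 1 and 4 after quantile normalization. The 4 genes, CXCL8, IL1B, CXCL3 and CXCL2, encode secreted inflammatory signals, and their levels were 6.77-fold, 2.79-fold, 2.47-fold and 2.10-fold lower. The groups did not overlap for 5921 genes, 32.65% of those tested where chance gives 10%. Fewer genes were called when any array was left out, namely 1070, 1402 and 980 without knockdown replicates 1, 2 and 3 and 1120, 981 and 1028 without control replicates 1, 2 and 3. With the replicate number as a block 1036 genes were called. The block keeps all 6 arrays but uses up some of the 4 residual degrees of freedom, so it also has less power.

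The other large falls included CSF3, a granulocyte growth factor (log2 fold change -0.98 ± 0.05, SE), MMP1, an interstitial collagenase (-0.95 ± 0.05), and HAS2, a hyaluronan synthase (-0.90 ± 0.07). DUSP6, a phosphatase that acts on ERK, fell by 0.87 and NFKBIZ, a nuclear regulator of NF-kB, by 0.82. TMEM50A, SLC25A13, a mitochondrial aspartate and glutamate carrier, and the keratin-associated gene KRTAP1-5 completed the 12 largest falls, at -0.91, -0.84 and -0.83. The largest rise was that of DEPTOR, an inhibitor of mTOR kinase, at 0.95 ± 0.07 or 1.93-fold. COL5A1, a fibrillar collagen chain, rose by 0.91 ± 0.05, ALPK2 by 0.85, and FZD2, a Wnt receptor, by 0.81. RPTN, FER1L4, RASD2, ANK1, OLFML2B, CSGALNACT1, DDIT4 and HOPX rose by 0.69 to 0.81. All 24 genes were chosen among called genes, and their highest adjusted p by limma was 0.00383, for RPTN. Their probe sets moved in the same direction within each gene. With the most variable probe set in place of the average, ANK1 was at 1.18.

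**Figure D2:**
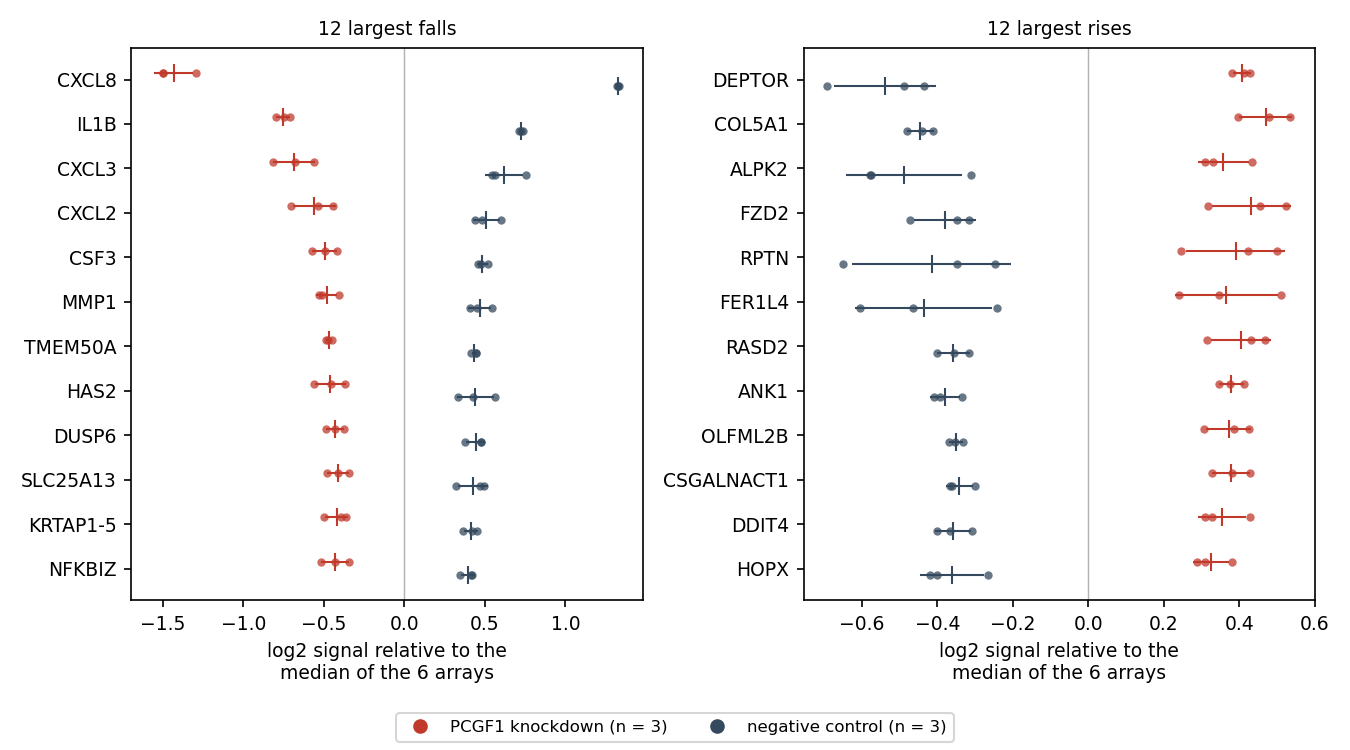
Log2 signal relative to the median of the 6 arrays (horizontal axes) for the 12 genes with the largest falls and the 12 with the largest rises, averaged over the probe sets of each gene. Points are arrays, ticks are means of 3 arrays and horizontal bars are SD. The 24 genes were chosen among called genes whose knockdown and control arrays do not overlap. CXCL8, with a log2 fold change of -2.76, lies farthest apart.

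Inflammatory genes had the largest median change of the 44 lists. Of 27 measured genes in the list of NF-kB and inflammatory genes, 19 fell, 0 rose and 8 did not pass the test, with the same counts when adjusted over the list alone. The median log2 fold change was -0.44 (95% interval -0.58 to -0.19), and the list was called lower (camera adjusted p = 1.34e-15, and adjusted p = 0.0303 with an estimated correlation). CXCL8, the neutrophil attractant interleukin-8, fell by 2.76 ± 0.06 (SE, 3 probe sets between -3.01 and -2.57), and IL1B, the cytokine interleukin-1 beta, by 1.48 ± 0.04. Among members chosen after their values were seen, TNFAIP3, an inhibitor of NF-kB signalling, fell by 0.70. PTGS2, the inducible cyclooxygenase, fell by 0.64, the cytokine genes LIF and IL1A by 0.63 and 0.45, and the chemokine gene CCL20 by 0.58. IL6 fell by 0.43 on average over 2 probe sets that disagreed, one at -0.99 and the other at 0.14. CXCL1 fell by 0.57 on average over probe sets at -0.96 and -0.18, and without the _s_at and _x_at probe sets its log2 fold change was -0.18 and did not pass (adjusted p = 0.0716). Of the 43 probe sets of the 16 list genes with several probe sets, 37 were lower in the knockdown arrays.

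The lists of DNA replication and mitosis genes were called lower with the preset correlation but not with an estimated one, and most of their members did not pass the test. Of 40 G1/S phase genes 16 fell and 0 rose (24 fell when adjusted over the list alone), with a median of -0.15, a list adjusted p = 8.38e-10 and an adjusted p = 0.0679 with an estimated correlation. Of 54 G2/M phase genes 22 fell and 0 rose (35 fell and 1 rose when adjusted over the list alone), with a median of -0.16, a list adjusted p = 3.59e-12 and an adjusted p = 0.0730 with an estimated correlation. RPA2, a subunit of the single-strand DNA binding protein RPA, fell by 0.42 ± 0.04 (SE) and RRM1, the large subunit of ribonucleotide reductase, by 0.29 ± 0.04. NUSAP1, a spindle-associated protein, fell by 0.61 ± 0.04 and HMMR, the hyaluronan-mediated motility receptor, by 0.34 ± 0.04. The mitotic kinase genes AURKB and BUB1, chosen after their values were seen, fell by 0.33 and 0.30. Among 22 cyclins, cyclin-dependent kinases and their inhibitors 1 rose and 4 fell, and this list was not called (adjusted p = 0.190). CCND1, cyclin D1, fell by 0.62 ± 0.05 while CDK6, one of its partner kinases, rose by 0.50 ± 0.05. The 3' minus 5' signal of the ACTB control probe sets was higher in the knockdown arrays by 0.0778 ± 0.0426 (SE) and that of GAPDH by 0.0203 ± 0.0164, with overlapping ranges between the groups in both.

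The lists of MYC targets and of genes downstream of ERK signalling were also called lower with the preset correlation and not with an estimated one, and most of their members were not called lower. In the MYC target list 11 of 30 genes fell and 0 rose (14 fell when adjusted over the list alone), with a median of -0.12 and a list adjusted p = 6.30e-07 that became an adjusted p = 0.0679 with an estimated correlation. ODC1, the first enzyme of polyamine synthesis, fell by 0.71 ± 0.04 (SE) and MYC itself by 0.58 ± 0.04. The nucleolar protein genes NOP58 and DKC1, chosen after their values were seen, fell by 0.29 and 0.27. Of 25 ERK feedback and immediate-early genes 10 fell and 3 rose (11 and 3 when adjusted over the list alone), with a median of -0.14, a list adjusted p = 0.000325 and an adjusted p = 0.147 with an estimated correlation. DUSP6 and CCND1 fell most. SPRY2 and EGR1, chosen after their values were seen, fell by 0.43 and 0.40, EGR1 by 0.80 with its most variable probe set. EPHA2, an ephrin receptor, rose by 0.40 ± 0.05, DUSP4, another ERK phosphatase and also chosen after its value was seen, by 0.26, and SPRY4 by 0.36 on average over 3 probe sets that disagreed, from -0.12 to 1.19. The list's median was -0.21 with the most variable probe sets.

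The lists of matrix genes and of the TGF-beta and BMP pathway were called higher with the preset correlation but not with an estimated one, and most of their members were not called higher. Of 37 collagens and matrix proteins 14 rose and 0 fell (17 rose when adjusted over the list alone), with a median of 0.12 and a list adjusted p = 5.87e-08, against an adjusted p = 0.0777 with an estimated correlation. COL5A1 rose most and COL1A1, a chain of type I collagen, rose by 0.61 ± 0.06 (SE). COL1A2, the small leucine-rich proteoglycan gene LUM and the collagen crosslinking enzyme LOX, chosen after their values were seen, rose by 0.60, 0.45 and 0.30. In the TGF-beta and BMP pathway list 12 of 31 genes rose and 3 fell (14 and 5 when adjusted over the list alone), with a median of 0.12, a list adjusted p = 0.00114 and an adjusted p = 0.0777 with an estimated correlation. ID3, a transcription inhibitor induced by BMP, rose by 0.60 ± 0.04 and SMAD6, an inhibitor of BMP signalling, by 0.39 ± 0.04. The ligand gene BMP2 fell by 0.37 ± 0.06 and the BMP antagonist gene GREM1 by 0.25 ± 0.04, the latter not passing with the most variable probe set of the gene (adjusted p = 0.0682). TGFB3 and the TGF-beta induced matrix gene TGFBI, chosen after their values were seen, rose by 0.34 and 0.30. Some of these averages hide wide differences in size between probe sets of the same sign. With the most variable probe set of each gene the log2 fold change was 0.95 for COL1A1, 1.16 for COL1A2, 0.49 for LOX, 0.79 for SMAD6 and 0.54 for TGFB3. Related lists were not called by camera with the preset correlation, although fry called the transition list described below (fry adjusted p = 0.00145). Of 30 matrix proteases and inhibitors 7 rose and 6 fell (list adjusted p = 0.490). MMP1 was at the low end and PLAT, tissue plasminogen activator, rose by 0.46 ± 0.04. Camera tests a net shift, so the opposite changes of this list can cancel in it. Of 19 epithelial-mesenchymal transition factors and markers 6 rose and 0 fell (list adjusted p = 0.122), among them the matrix genes SPARC at 0.56 ± 0.04 and FN1 at 0.34 ± 0.04. Of 23 integrins and adhesion receptors 5 rose and 2 fell (list adjusted p = 0.433), ITGA2 falling by 0.62 ± 0.06 and ITGA10 rising by 0.44 ± 0.04, or by 0.73 with its most variable probe set.

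Lists of stress and immune genes were called higher with the preset correlation and not with an estimated one. Of 34 interferon-stimulated genes 8 rose and 0 fell (12 rose and 1 fell when adjusted over the list alone), with a median of 0.08, a list adjusted p = 0.00123 and an adjusted p = 0.0777 with an estimated correlation. IFIT1, an RNA-binding antiviral protein, rose by 0.50 ± 0.06 (SE) and IFI35 by 0.34 ± 0.04. Of 21 antigen presentation genes 5 rose and 0 fell (10 rose when adjusted over the list alone), with a median of 0.12, a list adjusted p = 2.63e-05 and an adjusted p = 0.0777 with an estimated correlation. HLA-DMA, of the class II pathway, rose by 0.40 ± 0.04 and TAP1, a peptide transporter, by 0.35 ± 0.04. HLA-DPA1, a class II gene chosen after its value was seen, rose by 0.23. Of 28 hypoxia genes 9 rose and 3 fell (13 and 4 when adjusted over the list alone), with a median of 0.12, a list adjusted p = 0.000320 and an adjusted p = 0.0863 with an estimated correlation. DDIT4, a stress-induced inhibitor of mTOR complex 1, rose by 0.71 ± 0.05, P4HA1, a collagen prolyl hydroxylase, by 0.44 ± 0.05, and STC1, the hormone stanniocalcin, fell by 0.42 ± 0.07. With the most variable probe sets the median was 0.19 for antigen presentation and 0.18 for hypoxia.

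Of 18 glycolysis genes 3 rose and 1 fell (3 and 1 when adjusted over the list alone), with a median of 0.07, a list adjusted p = 0.00202 and an adjusted p = 0.384 with an estimated correlation. ALDOC and ENO2, the aldolase and enolase forms typical of brain, rose by 0.30 ± 0.04 and 0.29 ± 0.04 (SE), ALDOC not passing without the _s_at and _x_at probe sets (adjusted p = 0.0769). Of 26 p53 target genes 6 rose and 0 fell (9 rose when adjusted over the list alone), with a median of 0.07, a list adjusted p = 0.00828 and an adjusted p = 0.121 with an estimated correlation. SESN1 rose by 0.34 ± 0.07, a call lost without knockdown replicate 2 or 3 or control replicate 1 or 3 (adjusted p up to 0.0596). TRIAP1 rose by 0.27 ± 0.04, and without the _s_at and _x_at probe sets the list's median was 0.02 and its adjusted p 0.0581. Of 28 autophagy and lysosome genes 5 rose and 1 fell (8 and 1 when adjusted over the list alone), with a median of 0.05, a list adjusted p = 0.0232 and an adjusted p = 0.147 with an estimated correlation. CTSA, the lysosomal protective protein, rose by 0.30 ± 0.04, and the list's adjusted p was 0.0585 without knockdown replicate 3, 0.0962 with the most variable probe sets and 0.107 without the _s_at and _x_at probe sets. The medians were small and depended on the probe sets used, at 0.10, 0.12 and 0.11 for the 3 lists with the most variable probe sets, and 0.03 for the last list without the _s_at and _x_at probe sets.

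Lists of housekeeping complexes were called slightly lower with the preset correlation, and none of them with an estimated one. None of 37 cytosolic ribosomal protein genes passed the test on its own, 0 also when adjusted over the list alone, but 35 of them had negative fold changes, with a median of -0.06 (list adjusted p = 0.000768, and adjusted p = 0.422 with an estimated correlation). Of 27 proteasome subunits 2 fell, again 2 when adjusted over the list alone, with a median of -0.06, a list adjusted p = 0.0246 and an adjusted p = 0.378 with an estimated correlation. Without control replicate 3 the adjusted p of the proteasome list was 0.0515, with the most variable probe sets 0.0563, and without the _s_at and _x_at probe sets 0.0581. Of 16 replication-dependent histone genes 2 fell, again 2 when adjusted over the list alone, with a median of -0.12, a list adjusted p = 0.0212 and an adjusted p = 0.384 with an estimated correlation. The histone list also missed the threshold with fry (adjusted p = 0.0647), without knockdown replicate 1 (median -0.08, adjusted p = 0.0575), without control replicate 3 (adjusted p = 0.0626), with the most variable probe sets (adjusted p = 0.0637) and without the _s_at and _x_at probe sets (adjusted p = 0.434). Histone genes resemble each other closely enough for probes to be shared.

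**Figure D3:**
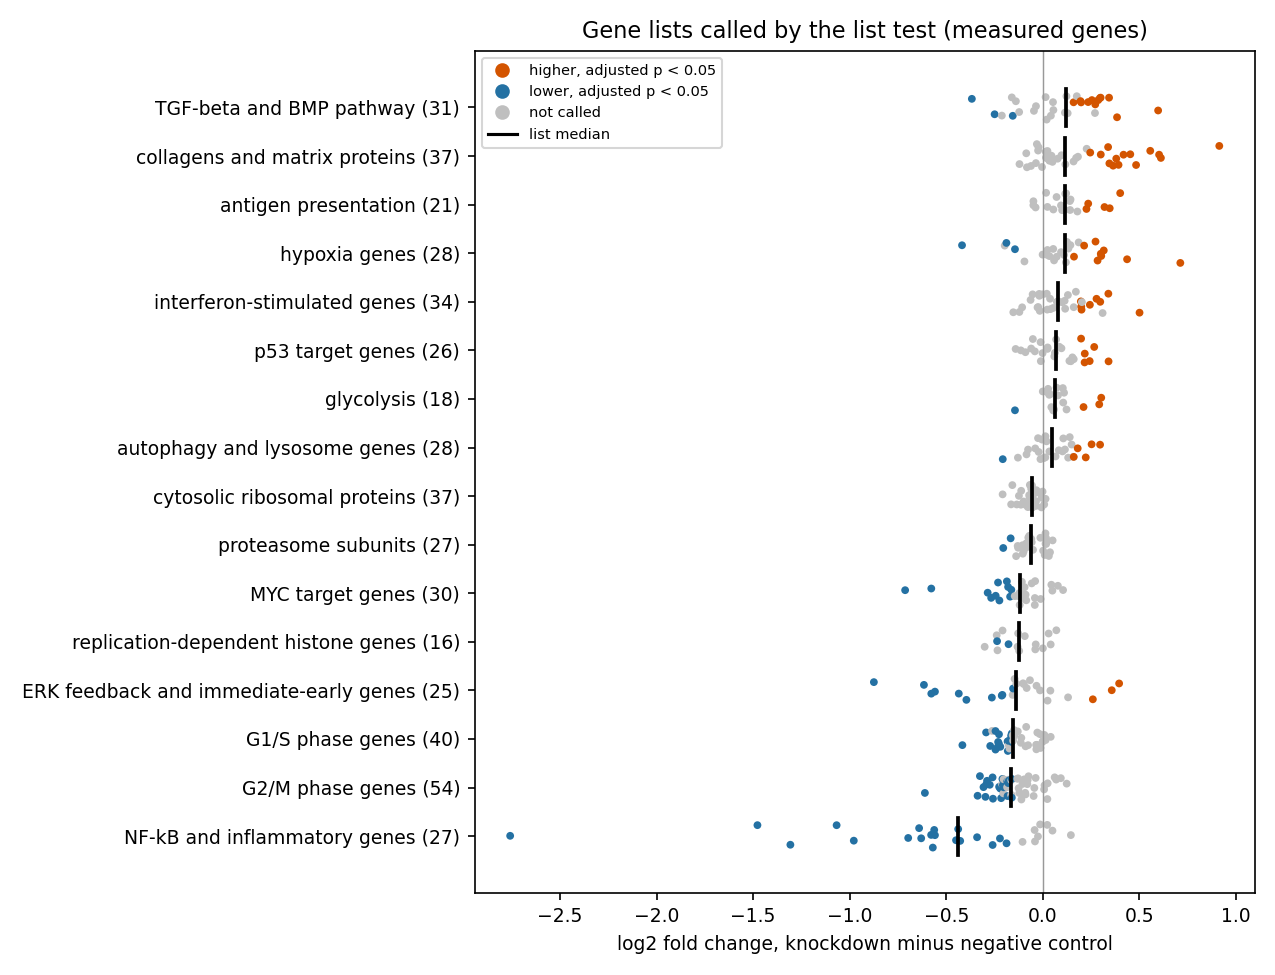
Log2 fold change, knockdown minus control (horizontal axis), of every measured member of the 16 called gene lists, with the number of measured genes in parentheses. Each point is a gene, orange for genes called higher, blue for genes called lower and grey for genes not called, and black bars are list medians, which run from -0.44 for the NF-kB and inflammatory genes to 0.12 for the TGF-beta and BMP pathway.

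Genes that Polycomb complexes are known to repress during development were not called as groups. Of 27 measured HOX genes 1 rose and 0 fell (list adjusted p = 0.965), the risen gene being HOXB2 at 0.35 ± 0.05 (SE). Of 75 developmental transcription factors 6 rose and 1 fell (list adjusted p = 0.664). IRX5 rose by 0.35 ± 0.04. The medians of both lists, -0.01 and -0.02, and their means, 0.01 and 0.01, differed in sign. Of 22 genes of retinoic acid metabolism and response 1 rose and 3 fell (list adjusted p = 0.664), with ALDH1A3, which makes retinoic acid, down by 0.41 ± 0.04 and DHRS9, a retinol dehydrogenase, by 0.33 ± 0.04.

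The lineage lists were not called either. Of 25 glioma stem cell markers 1 rose and 2 fell (list adjusted p = 0.755), ID3 and ALDH1A3 being the largest changes. Of 24 neuronal genes 4 rose and 2 fell (list adjusted p = 0.664). The secretory granule genes SCG5 and SCG2 moved in opposite directions, by -0.45 ± 0.05 and 0.44 ± 0.06 (SE). Of 17 astrocyte genes 1 rose and 1 fell (list adjusted p = 0.664), with CHI3L1, a secreted chitinase-like protein, up by 0.46 ± 0.05. Of 15 oligodendrocyte lineage genes 1 rose and 0 fell (list adjusted p = 0.573).

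The remaining signalling, survival and metabolic lists were also not called by camera with the preset correlation. Fry did call cholesterol biosynthesis (fry adjusted p = 0.0109), YAP/TEAD targets (0.0381), receptor tyrosine kinases (0.00513) and double-strand break repair (0.0216). For Wnt targets and regulators 5 of 26 rose and 2 fell (list adjusted p = 0.438), with SFRP2, a secreted Wnt modulator, up by 0.62 ± 0.08 (SE) beside FZD2. For YAP/TEAD targets 5 of 20 rose and 2 fell (list adjusted p = 0.0900), with CCN2, a matricellular protein, up by 0.29 ± 0.04 and F3, tissue factor, down by 0.33 ± 0.05, although F3 did not pass with its most variable probe set (adjusted p = 0.0728). For receptor tyrosine kinases 6 of 27 rose and 0 fell (list adjusted p = 0.116), with DDR2, a collagen receptor, up by 0.35 ± 0.04. For angiogenesis ligands and receptors 4 of 27 rose and 2 fell (list adjusted p = 0.777), for the Notch pathway 1 of 23 rose and 1 fell (list adjusted p = 0.852), and for the Hedgehog pathway 0 of 13 rose and 0 fell (list adjusted p = 0.664). For genes of the unfolded protein response and ATF4 5 of 34 rose and 6 fell (list adjusted p = 0.986). NUPR1, a stress-induced chromatin protein, rose by 0.36 ± 0.05. Across all genes 11% were called, and camera tests a net shift, so opposite changes in this list can cancel in it. The test's direction for that list was lower while its median, 0.00, and mean, 0.02, were above 0. For cholesterol biosynthesis 2 of 18 rose and 0 fell (list adjusted p = 0.0623), for oxidative phosphorylation 0 of 37 rose and 0 fell (list adjusted p = 0.622), for apoptosis regulators 1 of 23 rose and 1 fell (list adjusted p = 0.664), and for double-strand break repair 0 of 26 rose and 4 fell (list adjusted p = 0.0900). Median and mean differed in sign in 7 lists, those of HOX genes, developmental transcription factors, apoptosis regulators, angiogenesis, neuronal genes, astrocyte genes and the Notch pathway.

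Markers of cell types other than glioma cells were not called as groups by camera with the preset correlation. Among epithelial markers 0 of 19 rose and 0 fell (list adjusted p = 0.664). Among leukocyte markers 0 of 19 rose and 3 fell (list adjusted p = 0.0897), with LCP1, the actin-bundling protein plastin-2, down by 0.40 ± 0.04 (SE). The alternative test, fry, did call the leukocyte list (fry adjusted p = 0.0105). Among endothelial markers 1 of 12 rose and 0 fell (list adjusted p = 0.245), the risen gene being ENG, a TGF-beta co-receptor, at 0.30 ± 0.04. Of the 44 lists, 16 were called with the preset correlation, 8 higher and 8 lower, and with an estimated correlation only the inflammatory list was. Fry called 21 lists, 12 higher and 9 lower, of which 15 were also called by camera with the preset correlation. When adjusted over the list alone, members of the lists that were not called gave other counts in 12 cases. PRC2 subunits then had 1 higher and 4 lower, retinoic acid genes 2 and 3, apoptosis regulators 1 and 3, genes of the unfolded protein response and ATF4 5 and 9, and transition markers 6 and 2. Matrix proteases had 10 higher and 6 lower, integrins 6 and 3, angiogenesis genes 4 and 3, astrocyte genes 2 and 1, Notch pathway genes 0 and 0, YAP/TEAD targets 8 and 2, and receptor tyrosine kinases 8 and 0. The other lists not called had the same counts either way.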

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

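The tests below were set before their results were seen, except the interval around the share of probe sets and the reading of the result from it, which were added afterwards. The SE margin applied below to the control signal was also not in the rule set in advance. Outside the named genes, 97 probe sets that carry no gene symbol here were called higher in the knockdown arrays and 82 were called lower. They drew attention as signal in data that the gene comparison leaves out. However, 179 of the 2473 probe sets without a symbol were called, a share similar to 3571 of all 49293. The counts are therefore no excess, and these probe sets were not identified further.

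If behind the fall of the inflammatory genes, faulty single probe sets would leave the probe sets of a gene in disagreement, at under 70% negative by the bound set in advance, whereas 86.05% of 43 probe sets were negative (Wilson interval 72.7 to 93.4%, which treats probe sets as independent). That interval lies above 70% but also reaches below the 85% set in advance for sound probe sets, so the margin is narrow. The test covers only list genes with several probe sets, so it says nothing about those with 1, such as IL1B, CCL20 and IL1A. Probe sequences were not used, so probes shared between related genes such as CXCL1, CXCL2 and CXCL3 were not examined. A single deviating array is argued against by the list median, which kept at least 93.74% of its size in each of the 6 fits without 1 array. Culture state at harvest stays open, because 0 groups hold arrays of both sample names, T0 and T1, and so time or handling cannot be told apart from the knockdown. Lower PCGF1 or an unintended target of the hairpin may equally underlie the fall.

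The fall of the cell cycle genes was smaller, with a median of -0.16 over the 94 genes of both phase lists (95% interval -0.18 to -0.12). It is less certain, as 16 of 40 G1/S and 22 of 54 G2/M genes were called and neither list passed with an estimated correlation (adjusted p = 0.0679 and adjusted p = 0.0730). The median did not come from 1 array, since at least 90.1% of the median was kept without any single array. RNA quality or labelling length stays open and cannot be told apart from an effect of the knockdown. The rule set in advance excluded RNA quality for differences in 3' minus 5' control signal under a limit scaled to the list median. Here that limit was 0.0801. The differences of ACTB and GAPDH, 0.0778 ± 0.0426 (SE) and 0.0203 ± 0.0164, were both under it, but that of ACTB by less than its SE. The margin of 1 SE was not in that rule, and it is why the explanation stays open here. Cell number and growth rate were not used here, so a lower share of dividing cells may be a biological explanation but was not tested.

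Copy number differences between the 2 cell populations would shift the genes of whole chromosome segments together. Among 18108 genes placed in genomic order, 0 windows of 51 neighbouring genes had a median beyond the limit of 0.0794 that 1000 shuffles set, the largest being 0.0743, and such windows thus held 0% of the called genes. The window with the largest median came close to the limit and held 10 called genes, all of them higher. Thus no segment change large enough to move a window's median beyond that limit was seen. Genes that are not expressed would dilute such a median, and centred values do not allow them to be removed. Smaller shifts of long segments therefore stay open, and changes shorter than such a window were not examined.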

How the results depend on the processing

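The robust variance model, the most variable probe set per gene and the averaging without _s_at and _x_at probe sets were chosen after the data were seen. PCGF1 stayed lower under its 14 alternatives, with log2 fold changes from -0.48 to -0.39 and adjusted p from 0.00280 to 0.0195. Without averaging, 3571 of 49293 probe sets were called, a smaller share than the 1994 of 18132 genes. Against 1994 genes, 63 were called at 1.5-fold or more, 623 at an adjusted p under 0.01 and 73 when tested against a 1.2-fold change. Leaving out 1 array gave 980 to 1402 genes. The replicate block left 1036 genes, of which 1009 were among the 1994, all in the same direction. The replicate numbers did not pair the arrays, with residual correlations of -0.04, -0.06 and -0.00103, and 0 of 3 knockdown arrays correlated best with the control array of its number. At 2-fold or more, 4 genes became 15 with the most variable probe set per gene, 7 without _s_at and _x_at probe sets, and 24 as probe sets. The 16 called lists became 1 with an estimated correlation. Other settings kept these counts within 1.5 times, but not always the same genes. The most variable probe set per gene called 1474 genes, of which 1122 were among the 1994. Without the _s_at and _x_at probe sets 1360 genes were called, of which 1269 were among the 1994. All shared genes kept their direction. For the 24 largest changes, all 311 values under alternatives kept call and direction. These genes were chosen as the largest called changes on the same arrays, so this is not an independent check. For those with 1 probe set, choosing the most variable probe set changes nothing. Over all genes picked by the rule or chosen later, 1742 values stayed on the same side of the threshold, 203 no longer passed it and 3 newly passed. Reversals of direction were counted only for genes called in the main fit, with 0 found. Genes not called could change sign, as BCORL1 did, from -0.08 to 0.04 with single arrays left out. Several lost calls belong to genes not named elsewhere in the text, such as VEGFA and SLC2A1, which lost theirs whichever array was left out. For called lists 181 stayed and 27 no longer passed. Causes were not tested, beyond fewer arrays or stricter thresholds. The 2 filters on dim probe sets and the intensity trend were not run, since centred values carry no signal over background. Weak genes near background are therefore not separated from well measured ones.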

Other observations

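The grouping by gene family, the test of the union of HOX and developmental genes and the genes named here were chosen after results were seen, and the test of neighbouring genes was set before. Gene families were formed from symbols that share a stem, and 245 families of at least 10 measured genes were tested with camera. Of these, 3 were called, and 0 were called with an estimated correlation (adjusted p = 0.888 for each of the 3). Metallothioneins, small metal-binding proteins, were lower as a family (13 genes, 3 fell, adjusted p = 0.00115), with MT1X at -0.42 ± 0.04 (SE), MT1M at -0.39 ± 0.04 and MT1F at -0.29 ± 0.04. Nucleoporins, the proteins of the nuclear pore, were lower as well (24 genes, 6 fell, adjusted p = 0.00691), with NUP54 at -0.34 ± 0.04 and NUP37 at -0.31 ± 0.05. Protocadherin beta genes, a cluster of neuronal adhesion proteins, were higher (18 genes, 4 rose, adjusted p = 0.0194), with PCDHB14 at 0.47 ± 0.06. The calls of the other 3 risen members were less stable. PCDHB5 lost its call without control replicate 2 (adjusted p = 0.0552), PCDHB10 without knockdown replicate 1, knockdown replicate 3 or control replicate 1 (adjusted p up to 0.0604), and PCDHB6 when any array except knockdown replicate 3 was left out, with array weights, with the replicate number as a block and without the _s_at and _x_at probe sets (adjusted p up to 0.372). Metallothionein and protocadherin genes are close copies of each other, so which member changed is uncertain.

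Called genes of the same direction lay next to each other in the genome more often than in shuffled orders. There were 165 neighbouring pairs that changed the same way, against a mean of 112.1 and a 95th percentile of 129 in 1000 shuffles, and 101 pairs that changed in opposite ways, against a mean of 107.3. The runs included the complement protease genes C1S, at 0.39 ± 0.04 (SE), and C1R, whose call was lost without knockdown replicate 3, control replicate 2 or control replicate 3 and with the replicate number as a block (adjusted p up to 0.0633). They also included the matrix metalloproteinase genes MMP10, MMP1 and MMP3, at -0.24, -0.95 and -0.36, and the interleukin-1 genes IL1A and IL1B. A candidate explanation is that neighbours share regulatory elements. Duplicated genes with a common ancestry and probes that match overlapping transcripts may add such pairs too, and these were not separated.

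A hypothesis that lower PCGF1 raises silent Polycomb target genes as a class was tested on the union of the HOX and developmental transcription factor lists. Of 102 measured genes 7 rose and 1 fell, the median log2 fold change was -0.0132 (95% interval -0.0311 to 0.00445), and limma's camera gave an adjusted p of 0.965 and 0.664 for the separate lists and a p of 0.599 for the union. No general rise was detected, but the hypothesis stays open, since silent genes may lie near the floor of the arrays, which centred values do not show, and PCGF1 transcript remained at 74.3% of control. Single genes that rose, such as HOXB2 and IRX5, may still respond.

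Other splits of the 6 arrays put the counts in context. There are 10 splits into 3 and 3, and 1 of them, the real one, gave as many genes, as many genes at 2-fold and as many lists as reported, which is too few splits for a share under 0.05. The real split called 1994 genes and 4 at 2-fold, and the highest of the others called 0 of either. For lists the real split gave 16 and the highest of the others 9, so lists were called with the preset correlation where no gene was. Every other split mixes arrays of both groups, so it keeps part of the difference between them and adds the rest to the spread. The other splits therefore do not show how many genes or lists would be called without any difference.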
